A study of Homo sapiens with 4 samples.

How the data were processed

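Total RNA of THP-1 cells, an established human line grown from an acute monocytic leukaemia, was labelled with biotin and hybridised to 4 Affymetrix expression arrays, per the labels' protocols. The deposited table holds 54675 probe sets, short sets of probes that each read part of a transcript, with 1 column per array. Per the submitters' processing notes, the values were made with RMA in affy 1.28.1. RMA corrects the background, forces the arrays to a common distribution and summarises the probes of a set as a log2 value. The deposited values fitted that description: they are log2 values between 2.54 and 15.22, and the sorted columns differed from each other by at most 0.11. Because of the common distribution, a global rise or fall in RNA content cannot be seen in these values, and small differences at low level are compressed toward 0. No array image values or detection calls were used here, so signal over background was judged only by level.

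Each array was placed in a group from its source label: resting cells, cells treated with Pam3CSK4, and cells kept together with platelet-like particles over 12 h or over 24 h. Pam3CSK4 is a synthetic lipopeptide that activates the receptor pair of TLR1 and TLR2. Per the series design, the co-cultured cells had also received Pam3CSK4. The sample titles of the co-culture arrays carry 13 and 25, while their descriptions give 12 h and 24 h, and the descriptions were used. How long the cells of the Pam3CSK4 array were treated is not given in the sources used here. No columns were left unmapped.

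Gene names came from a platform annotation table in which 41091 probe sets name 1 gene, 1801 name several and 11721 are not listed, after 62 control probe sets were set aside. Gene identifiers of 41043 of the 41091 were found in the RefSeq table of human assembly GRCh38.p14, which updated 0 symbols. No coordinates are printed, since the array table names no genome build. A gene was represented by its probe set of highest mean over the 4 arrays among probe sets naming that gene alone, which gave 19775 genes. Near-identical globin pairs with no probe set of their own were reported as the pair. A gene entered a comparison where its probe set reached the median of all values, 6.19, on at least 1 array, which left 13410 genes.

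With 1 array per group no test was possible, and no p-value or standard error was computed. Each comparison is the difference of 2 log2 values, and genes were counted as higher or lower at a difference of at least 2-fold, 1 on the log2 scale. Gene lists, 32 in number, were described by the median difference of their measured members and its percentile among 10000 random lists of the same size matched on mean level in 20 bins. A member counted as measured where it passed the filter on at least 1 array. Members with signal on treated cells only were thus kept, and silent members were not. A list was said to stand apart below percentile 2.5 or above 97.5, which describes these arrays and is not a test of the treatment. For genes with several probe sets above the filter, the range of their differences was kept as the available measure of precision.

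Groups, gene lists, thresholds and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 12 genes with the largest positive and the 12 with the largest negative difference whose other probe sets shared the sign. It added members of the lists central to a comparison that differed at least 2-fold, 4 leading members of any other list that stood apart, TLR1, TLR2 and TLR6 for Pam3CSK4, and ACTB and GAPDH. Y-linked genes and XIST were left out. Genes named outside the rule are said to be chosen after their values were seen.

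The 2 co-culture comparisons share the Pam3CSK4 array. A correlation across genes between them was therefore set beside 100 simulations of unchanged arrays with a shared control, with the same spread of 0.08 log2 on each array, taken from the comparison of the 24 h and Pam3CSK4 arrays. The shared control could not be split.

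The alternatives were no filter, a filter at the 75th percentile of values, the mean of a gene's probe sets, omission of probe sets with the suffix _x_at or _s_at that can bind related transcripts, cyclic loess on top of the deposited values (limma 3.58.1 in R 4.3.3, 3 iterations), and thresholds of 1.5-fold and 3-fold. The smallest difference over a gene's probe sets was added after the data had been seen. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

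The counting was tested on simulated arrays for the comparison of the 12 h and Pam3CSK4 arrays, with 50 genes raised at each fold size. Genes raised 2.5-fold, 4-fold or 8-fold were counted in 100% of cases, genes raised 1.5-fold in 0%, and 12868 unchanged genes in 0%. Of 200 unchanged lists of 18 genes, 4.0% stood apart, as did 100% of 50 lists shifted upward by 0.2 log2. The simulated noise was 0.08 log2 per array, taken from the comparison of the 24 h and Pam3CSK4 arrays. Across genes, differences spread by 0.12 in that comparison and by 0.23 at 12 h. These rates therefore check the computation and do not describe the 12 h counts.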

Results

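Gene expression was measured in THP-1 cells in 4 conditions, with 1 array each and no replicates. One array held resting cells and another cells activated with the TLR1 and TLR2 ligand Pam3CSK4. The other arrays held Pam3CSK4-treated cells after 12 h or 24 h with platelet-like particles, whose source cells the labels do not name. The number of arrays limits the precision of every difference: there is no spread between cultures to set it against. The median value was 6.19 on the resting array, 6.18 with Pam3CSK4, 6.22 at 12 h and 6.17 at 24 h. Across probe sets, the Pam3CSK4 and 24 h arrays were closest (Spearman 0.997), against 0.993 for Pam3CSK4 and 12 h and 0.984 for resting and Pam3CSK4. The gap between the 3' and 5' control probe sets of GAPDH, a measure of RNA integrity, was 2.16 log2 on the resting array. It was 0.59 with Pam3CSK4, 0.92 at 12 h and 0.70 at 24 h. The same gap for ACTB was wider on every array and differed less between them. It was 3.41 on the resting array, 2.91 with Pam3CSK4, 3.17 at 12 h and 2.90 at 24 h.

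The first comparison asked what Pam3CSK4 alone did to the monocytic cells. The gene with the largest difference between the Pam3CSK4 and resting arrays was CXCL13, a B-cell attractant, which went from 2.93 to 11.43 log2, a difference of 8.50. Its resting value lay below the 1st percentile of that array, 2.95, so the exact size of the difference depends on background. ADAMDEC1, a metalloproteinase-like protein of macrophages, differed by 7.25, IGFBP3, a carrier of insulin-like growth factors, by 6.74 and the hyaluronan-binding protein TNFAIP6 by 6.21. Across the 13410 genes, 555 were at least 2-fold higher and 229 at least 2-fold lower. Of the 555, 164 had a resting value under the filter level of 6.19, where signal over background was not established, and the exact size of such differences depends on background.

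Chemokines formed the most displaced list, with a median difference of 3.57 log2. Of 23 listed members 12 were measured, and of these 9 were at least 2-fold higher, 1 was lower and 2 differed less. CCL2, CCL4, CCL8, CCL20, CXCL1, CXCL2, CXCL3 and CXCL10 were under the filter level in resting cells. The exact size of their differences thus depends on background, and the share is not one of the whole list. CCL2, which recruits monocytes, differed by 5.78, CCL4 by 5.16, CXCL10 by 4.79 and the neutrophil attractant CXCL8 by 4.74, while CCL23 stood at -1.62. Negative-feedback and target genes of NF-kB had a median of 2.13, with 14 of 18 at least 2-fold higher and 0 lower. Among them the inhibitor gene NFKBIA differed by 3.07, TNFAIP3, a deubiquitinase that limits the pathway, by 2.97, and the survival gene BCL2A1 by 4.34. The cytokine list, with 17 of 24 members measured, had a lower median, 0.38, and 6 of the 17 were at least 2-fold higher. These were EBI3 at 6.18, IL1B at 3.96, TNF at 3.19, IL23A at 1.41, TNFSF13B at 1.35 and IL1RN at 1.13. The 3 lists lay at percentiles 100, 100 and 99.99 of matched random lists.

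Interferon-induced genes were higher nearly throughout, with 29 of 30 at least 2-fold higher and a median of 2.10. IFI44L differed by 4.96, IFI44 by 4.63, TRIM22 by 4.21 and the antiviral GTPase gene MX1 by 4.07. Monocyte genes had a median of 1.01, with 11 of 21 at least 2-fold higher and 1 lower. The calgranulin gene S100A12 differed by 5.97, CYBB, which encodes a subunit of the phagocyte oxidase, by 4.61, and the fungal glucan receptor CLEC7A by 3.89. In the antigen presentation list 10 of 20 were at least 2-fold higher (median 0.93), led by HLA-DRA at 3.89 and HLA-DQA1 at 2.48. In the coagulation and adhesion list 9 of 19 were higher and 1 lower (median 0.72), including ICAM1 at 3.70 and VCAM1, which went from 4.60, under the filter level, to 9.05. Toll-like receptor signalling genes had a median of 0.47, with 5 of 18 higher, led by TLR8 at 5.46 and LY96, the co-receptor of TLR4, at 4.37. Of the receptors of the ligand, TLR1 went from 4.38 to 5.97, both under the filter level, while TLR2 differed by 0.997, just under 2-fold, and TLR6 by 0.82, from 5.70.

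Genes of immature myeloid cells were lower. In that list 7 of 15 were at least 2-fold lower, 0 were higher, and the median was -0.66. MS4A3, a membrane protein of granulocyte and monocyte progenitors, differed by -3.65, PRTN3, a protease of granules, by -1.82 and MPO by -1.49. KIT, the receptor of stem cell factor, was 3.99-fold lower. Other leading lower genes were CEACAM6 at -3.40, STAR, which moves cholesterol into mitochondria, at -2.80, the defensin gene DEFB1 at -2.68 and the iron exporter gene SLC40A1 at -2.42. WDR49 stood at -3.48, STYXL2 at -3.22 and ANKRD55 at -2.72.

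Other lists were shifted as well. Inflammasome genes had a median of 0.53, with 4 of 12 at least 2-fold higher, including CASP5 at 1.63 and NLRC4 at 1.52. Lysosomal genes had a median of 0.49 with 4 of 21 higher, led by CTSH at 2.41, histone genes 0.47 with 2 of 7, and metallothioneins 0.45 with 2 of 8. Macrophage genes had a median of 0.34 with 4 of 20 higher and 1 lower, immediate early genes 0.28 with 7 of 22 higher, and matrix-remodelling genes 0.27 with 3 of 13 higher, including MMP9 at 5.94. Hypoxia and glycolysis genes (0.19), sterol synthesis genes (0.18), NRF2 and iron genes (0.17) and p53 targets (0.13) also stood above matched random lists, with HMOX1 at 2.70 and CDKN1A at 1.19. Below matched lists were LXR and lipid genes at -0.32, unfolded-protein genes at -0.28 and megakaryocyte and platelet genes at -0.18, where 1 of 20 was at least 2-fold lower, NFE2 at -1.21. Inside the range of matched lists were cell cycle genes at -0.04, ribosomal proteins at -0.06, oxidative phosphorylation genes at -0.07, heat shock genes at -0.07, globin and erythroid genes at -0.01, lymphocyte genes at -0.05, endothelial genes at -0.18 and reference genes at 0.13. Fibroblast and epithelial genes were inside as well, with a median of -0.13 and a mean of 0.35, which differ in sign. ACTB differed by 0.13 and GAPDH by 0.32. With probe sets averaged, macrophage genes (0.13), hypoxia and glycolysis genes (0.10) and p53 targets (0.10) were inside the range. Histone genes were at 0.07 and inside with no filter, and without _x_at and _s_at probe sets LXR and lipid genes (-0.26), unfolded-protein genes (-0.17), sterol synthesis genes (0.13) and megakaryocyte and platelet genes (-0.17) were inside.

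The resting array carried the widest gap between the GAPDH control probe sets, so RNA integrity differed along with the treatment for each of these gene groups. Of 254 higher genes with several probe sets, 232 had a single sign across them, with a median range of 0.82 log2. CXCL14 ranged from 0.26 to 6.21 over its probe sets above the filter. Of the genes named above, ICAM1 ranged from 0.83 to 5.16, CXCL8 from 2.08 to 4.74 and IL1RN from 0.18 to 1.13.

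**Figure D1:**
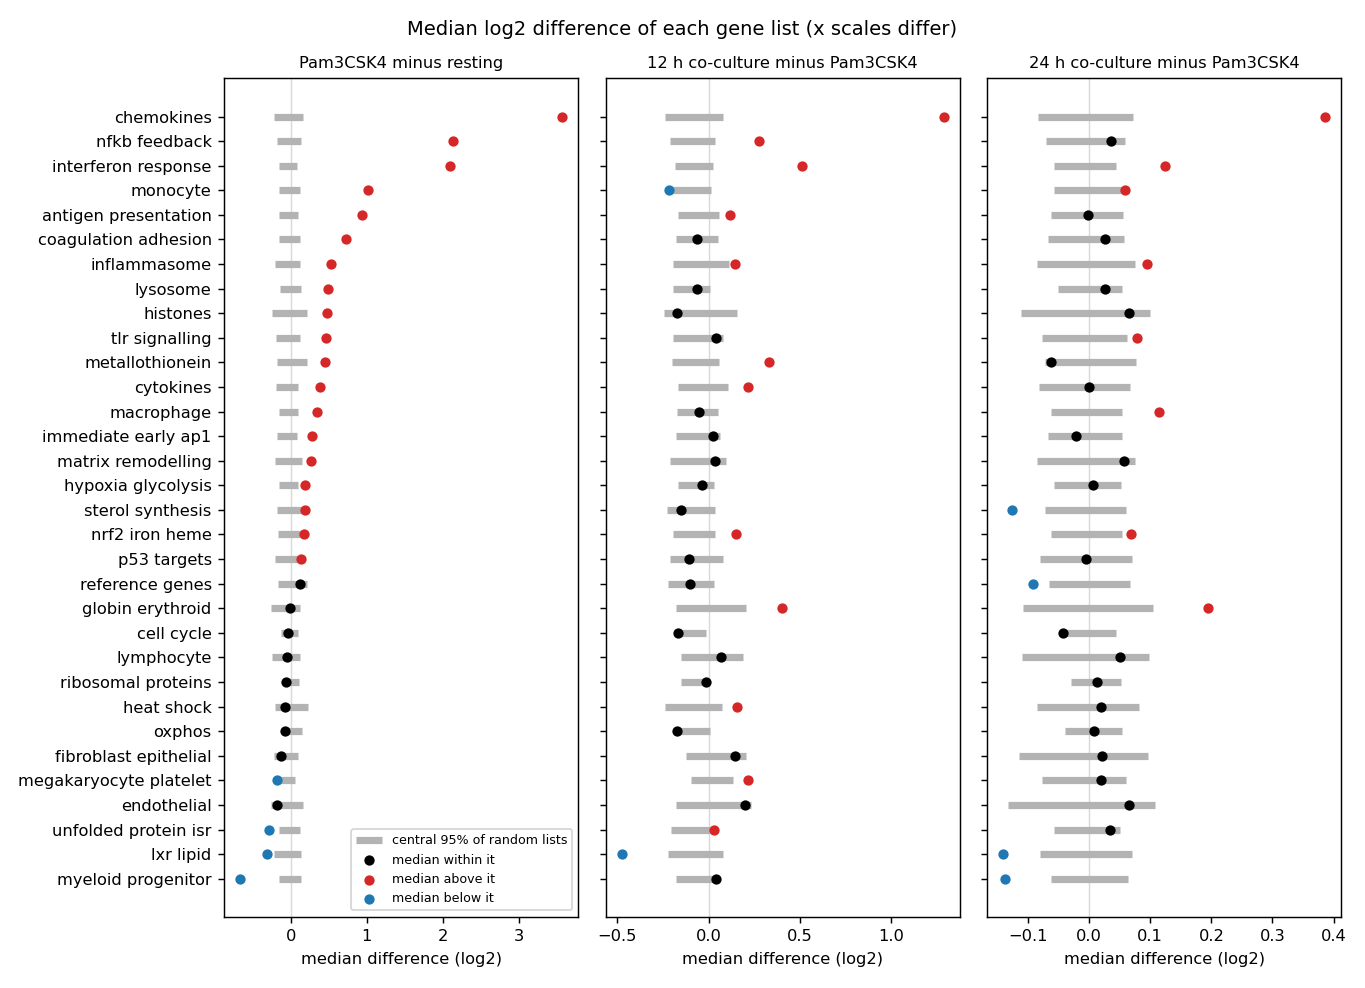
Median log2 difference of each of the 32 gene lists in 3 comparisons (points), with the central 95% of random lists matched on level (grey bars); the x scales differ. Chemokines have the highest median in each panel, at 3.57, 1.29 and 0.39, and globin and erythroid genes are above the grey bar in the co-culture panels at 0.40 and 0.19.

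The next comparison asked what 12 h with the particles added to Pam3CSK4 treatment. Gamma globin, a fetal haemoglobin chain, was higher on the 12 h array on each of the 3 probe sets that read HBG1 and HBG2 together. The differences ran from 2.62 to 4.04 log2, from Pam3CSK4 values of 6.57 down to 5.29. The smallest, 6.17-fold, was that of the probe set above the filter level with Pam3CSK4, and the other 2 were under it. COXFA4L3, a small mitochondrial protein gene also known as C15orf48, went from 4.75 to 7.75 log2 and the calcium-binding protein gene CALB1 from 3.68 to 6.59. Their Pam3CSK4 values lay near or under the 25th percentile of that array, 4.71, so no exact fold is given. LAMP3, a lysosomal membrane protein of mature dendritic cells, was 5.58-fold higher. Of 13410 genes, 55 were at least 2-fold higher and 47 lower.

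Chemokines were again the most displaced list, with 9 of 12 at least 2-fold higher than with Pam3CSK4 alone, 0 lower and a median of 1.29. CCL8 went from 9.20 to 11.50, CXCL8 from 11.01 to 12.80, CXCL2 from 8.47 to 10.25 and CXCL1 from 10.25 to 11.79. CXCL6, a neutrophil attractant outside the list, differed by 2.16. Other inflammatory lists were shifted by less. Interferon-induced genes had a median of 0.51 with 3 of 30 at least 2-fold higher, namely IFI44L at 1.30, OAS3 at 1.23 and RSAD2 at 1.01. NF-kB genes had a median of 0.28 with 1 of 18 higher, BCL2A1 at 1.02. Cytokines had a median of 0.21 with 0 of 17 at least 2-fold different, and IL1B stood at 0.78.

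The globin and erythroid list named 26 genes, of which 9 entries were measured, each pair counting as 1. Of the 9, 1 was at least 2-fold higher, the HBG1 and HBG2 pair, and the median was 0.40, at percentile 99.99. Embryonic epsilon globin, HBE1, differed by 0.85 and the carbonic anhydrase gene CA1 by 0.83. The megakaryocyte and platelet list, with 20 of 32 members measured, had a median of 0.22, at percentile 99.95, and 0 of the 20 were at least 2-fold different. Its leading members were TREML1 at 0.54, the platelet selectin SELP at 0.51, GNG11 at 0.39 and GP1BA at 0.38, each with a value under 8 log2 on every array. With probe sets averaged, that median was 0.10 and no longer stood apart from matched lists. The globin median was 0.16 and inside the range without _x_at and _s_at probe sets, which leave the HBG pair with no value.

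Further lists above matched random lists were metallothioneins at 0.33, heat shock genes at 0.16, NRF2 and iron genes at 0.15, inflammasome genes at 0.14, antigen presentation genes at 0.12 and unfolded-protein genes at 0.03. CD80, a T-cell co-stimulator, differed by 1.19, the paired HSPA1A and HSPA1B by 0.81, SRXN1 by 0.90 and DDIT3 by 0.72. LXR and lipid genes were below matched lists at -0.48, with 0 of 14 at least 2-fold different and the cholesterol exporter gene ABCA1 at -0.64. Monocyte genes were below at -0.22, with 2 of 21 at least 2-fold lower: CD14, the lipopolysaccharide co-receptor, at -1.18 and MNDA at -1.16. The monocyte median was -0.13 with no filter and -0.09 with probe sets averaged, and no longer stood apart in either setting. Without the _x_at and _s_at probe sets the monocyte median was 0.06 and the unfolded-protein median -0.03, each of the opposite sign, and heat shock genes, at 0.19, were inside the range. The other 18 lists, cell cycle genes (-0.17) among them, were inside the range. Some of them stood apart under an alternative: with cyclic loess cell cycle genes (-0.10) and immature myeloid genes (0.14), with probe sets averaged immediate early genes (0.08) and fibroblast and epithelial genes (0.29). Matrix-remodelling genes (0.12) and macrophage genes (0.07, against -0.06) did so with a 75th percentile filter, and lysosomal genes (0.12, against -0.06) without _x_at and _s_at probe sets.

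The leading lower genes at 12 h were BMP8B, a bone morphogenetic protein gene that was 4.01-fold lower, PLS3, an actin bundler, at -1.91, the carbonic anhydrase gene CA2 at -1.68, RIPOR2 at -1.68 and the histidine-degrading enzyme gene HAL at -1.60. LGR4 stood at -1.48, DHRS9 at -1.35 and BTK, a kinase of B-cell and myeloid receptors, at -1.32. Several of these differences were smaller on another probe set above the filter. The smallest was -0.17 for BMP8B, -0.61 for RIPOR2, -0.68 for HAL and -0.09 for LGR4. DHRS9 ranged from -1.93 to -1.35, and PLS3, CA2 and BTK had 1 such probe set each. Among other higher genes, SLAMF7 differed by 1.83, NPTX1 by 1.76, the protease inhibitor gene SERPINE2 by 1.74 and COL8A1 by 1.64. SLAMF7 ranged from 0.85 to 1.83 over its 3 probe sets above the filter. ACTB stood at -0.10 and GAPDH at -0.18. Averaged over probe sets, CXCL2 differed by 0.70, OAS3 by 0.60, RSAD2 by 0.77, HAL by -0.74 and LGR4 by -0.51, all under 2-fold, and the count of lower genes was 26. The control gap of GAPDH was 0.92 at 12 h against 0.59 with Pam3CSK4. Whether the Pam3CSK4 array matches the 12 h array in time is not known, so time and particles were not separated.

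**Figure D2:**
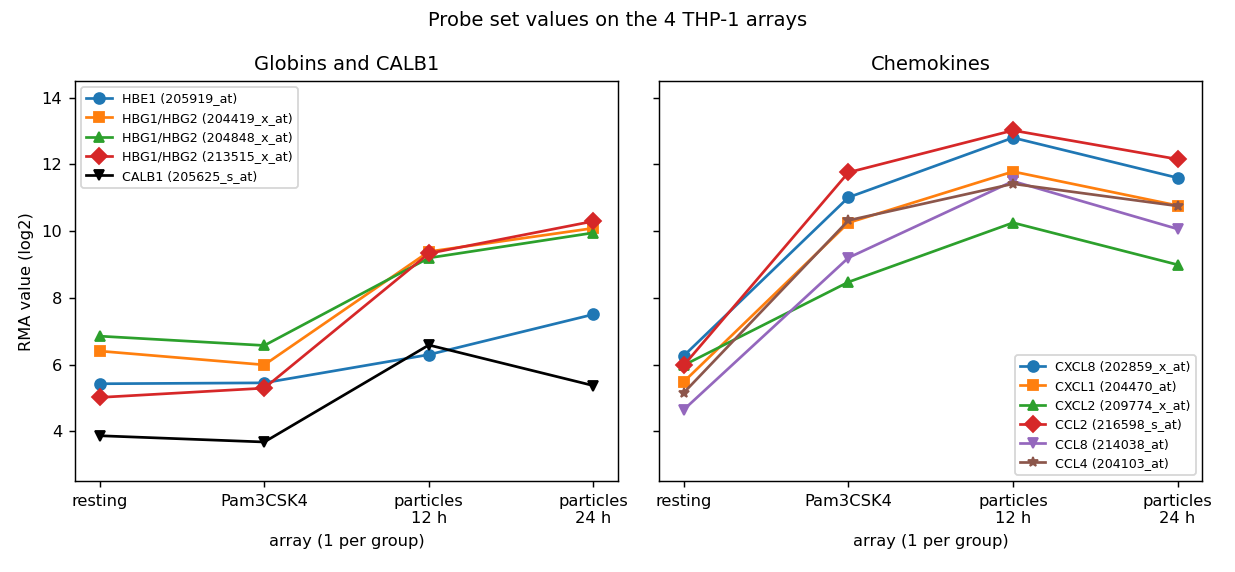
RMA values (log2) on the 4 arrays, 1 point per array, for probe sets of HBE1, HBG1/HBG2 and CALB1 (left) and for 6 chemokines (right). The HBG1/HBG2 probe sets lie between 5.01 and 6.85 on the resting and Pam3CSK4 arrays and between 9.20 and 10.30 on the co-culture arrays, while the 6 chemokines are highest at 12 h.

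After 24 h with the particles, the array was close to that of Pam3CSK4 alone apart from globins and a few genes. The HBG1 and HBG2 probe sets differed by at least 3.38 log2, or 10.4-fold, the value of the probe set that was above the filter level with Pam3CSK4. HBE1 went from 5.45 to 7.50, a difference of 2.05, on 1 of its 2 probe sets. Its other probe set, under the filter, differed by 0.0085. Of 13410 genes, 4 were at least 2-fold higher and 0 lower: HBE1, CALB1, which went from 3.68 to 5.37, the tryptophan-degrading enzyme gene TDO2 at 1.14 and SOCS2, a suppressor of cytokine signalling, at 2.01-fold. For 3 of the 4, HBE1, CALB1 and SOCS2, the Pam3CSK4 value was under the filter level, so the exact size depends on background.

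Other globins were nearer to their Pam3CSK4 level. The 6 probe sets of HBA1 and HBA2 differed by 0.12 to 1.70 at 24 h, and by 0.10 to 1.26 at 12 h. Adult beta globin, HBB, and HBD, both named here after their values were seen, differed by -0.15 to 0.0097 over 4 probe sets and by -0.12 at 24 h. At 12 h they had differed by -0.0050 to 0.44, with 0.44 and 0.40 on 2 of the HBB probe sets, and by 0.02. The globin and erythroid list had 2 of 9 members at least 2-fold higher, HBE1 and the HBG pair, 0 lower and a median of 0.19, at percentile 99.92. That median was -0.0097 with no filter, -0.05 with probe sets averaged and -0.0009 without _x_at and _s_at probe sets, so its sign rested on which members were counted. The megakaryocyte and platelet list had a median of 0.02, inside the range of matched lists, with 0 of 20 at least 2-fold different. With no filter that median was 0.08 and stood above matched lists.

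Chemokines had a median of 0.39 at 24 h, at percentile 100, with 0 of 12 at least 2-fold different; CCL8 led at 0.86, then CXCL8 at 0.59. Interferon-induced genes (0.12), macrophage genes (0.11), inflammasome genes (0.09), Toll-like receptor signalling genes (0.08), NRF2 and iron genes (0.07) and monocyte genes (0.06) were also above matched lists, with no member at least 2-fold different. APOC1, an apolipoprotein, differed by 0.63, SPP1 by 0.58 and GPNMB by 0.50. Below matched lists were LXR and lipid genes (-0.14), immature myeloid genes (-0.14), sterol synthesis genes (-0.13) and reference genes (-0.09), with KIT at -0.32 and SREBF2, the sterol-regulated transcription factor gene, at -0.33. Without _x_at and _s_at probe sets the LXR and lipid median was 0.04, of the opposite sign. Inflammasome genes (0.05 with a 75th percentile filter), Toll-like receptor signalling genes (0.02 averaged), and monocyte genes and reference genes (0.06 and -0.09 without those probe sets) were inside the range under those settings. The other 20 lists were inside the range, among them NF-kB genes at 0.04 and cytokines at 0.00. Lymphocyte genes (0.11 averaged), histone genes (0.09 with no filter), and matrix-remodelling and lysosomal genes (0.13 and 0.07 without those probe sets) stood apart under those settings. ACTB stood at -0.11 and GAPDH at -0.14. With probe sets averaged or a 75th percentile filter, the count of higher genes was 1, and TDO2 stood at 0.70 when averaged.

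**Figure D3:**
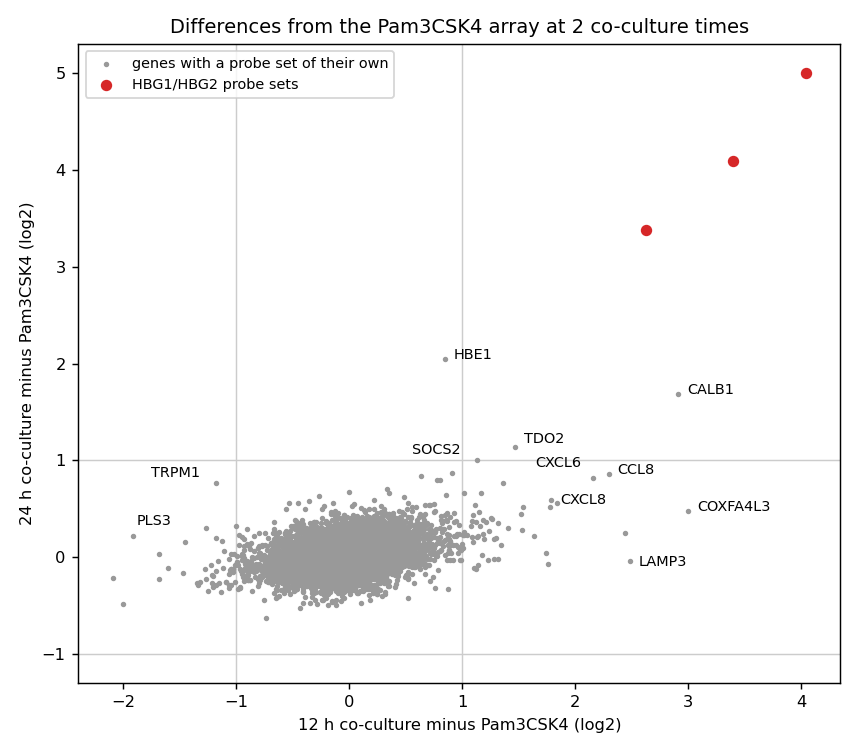
Log2 difference from the Pam3CSK4 array at 12 h (x) and 24 h (y) of co-culture for 13410 genes (grey) and the 3 HBG1/HBG2 probe sets (red); lines mark 2-fold. The red points lie at 2.62 to 4.04 on the x axis and at 3.38 or more on the y axis, away from the other genes.

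The 24 h array was then set against the 12 h array. As the 24 h array was close to the Pam3CSK4 array and the 12 h array is shared, this comparison largely mirrors that of 12 h with Pam3CSK4. COXFA4L3 and LAMP3 were lower at 24 h by the same -2.52 log2, HMGN2P46, a pseudogene transcript, stood at -2.19, NPTX1 at -1.84 and SERPINE2 at -1.69. Higher at 24 h were PLS3 at 2.13, the cation channel gene TRPM1 at 1.95, RIPOR2 at 1.71, TRIM58 at 1.57 and BMP8B at 1.51, with CD14 at 1.38 and HBE1 at 1.21. Over probe sets above the filter, TRPM1 ranged from 0.86 to 1.95, RIPOR2 from 0.61 to 1.71 and BMP8B from 0.19 to 1.51. At least 2-fold higher were 46 genes and lower 30, a split that was 35 and 35 after cyclic loess.

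Of the chemokines, 6 of 12 were at least 2-fold lower at 24 h than at 12 h, with a median of -0.94, led by CCL8 at -1.43, CCL22 at -1.33 and CXCL2 at -1.26. Metallothioneins had a median of -0.43 with 0 of 8 at least 2-fold different. Interferon-induced genes had a median of -0.37 with 2 of 30 lower, OAS3 at -1.26 and IFI44L at -1.11. NF-kB genes stood at -0.28, cytokines at -0.17, immature myeloid genes at -0.12 with KIT at -1.08, antigen presentation genes at -0.08 and NRF2 and iron genes at -0.08, each below matched lists. The NRF2 and iron median was 0.03 with probe sets averaged, of the opposite sign. LXR and lipid genes, at 0.33 with ABCA1 at 0.82, and monocyte genes, at 0.26 with 2 of 21 at least 2-fold higher, were above. Monocyte genes (0.16) were inside the range when averaged, as were immature myeloid genes (-0.06) and NRF2 and iron genes (-0.01) with no filter. Without _x_at and _s_at probe sets LXR and lipid genes (0.17), monocyte genes (0.06) and immature myeloid genes (-0.05) were inside the range. That setting put apart megakaryocyte and platelet genes (-0.20), coagulation and adhesion genes (0.22) and lysosomal genes (-0.08, against 0.13), and averaging did so for immediate early genes (-0.07, against 0.04). ACTB stood at -0.01 and GAPDH at 0.05. Averaged over probe sets, the count of higher genes was 21, and BMP8B (0.99), CXCL2 (-0.57) and OAS3 (-0.67) were under 2-fold.

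The 2 co-culture arrays were also compared for a shared pattern against the Pam3CSK4 array. Besides the HBG1 and HBG2 pair, which is outside the 13410 genes, CALB1, TDO2 and SOCS2 were at least 2-fold higher at both times, 3 genes in all. Independent lists of these sizes would share 0.0164 genes, which is not the value for no change, because the lists share the Pam3CSK4 array. At 12 h TDO2 had differed by 1.47 and SOCS2 by 1.13. SOCS2 stood at 6.72 on the resting array, above its co-culture values of 6.35 and 6.23. Of the 55 genes higher at 12 h, 47 were above 0 at 24 h, with a median of 0.28, and of the 47 lower genes 36 were below 0, with a median of -0.16. Across the 13410 genes, which are not independent replicates, the differences correlated with Pearson r of 0.30 and Spearman rho of 0.24. A shared control alone gives a positive r, 0.50 in simulations with equal spread on every array, and less where a co-culture array spreads more, as the 12 h array did. The covariance was 0.0121 against a simulated 0.0071, which rests on the spread assumed for the Pam3CSK4 array. With 1 control array, which could not be split, neither comparison tells a shared response from the shared array.

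Genes that differed between Pam3CSK4 and resting cells were then followed. The 555 higher genes had a median of 0.20 at 12 h relative to Pam3CSK4, with 385 above 0, and 0.06 at 24 h, with 362 above 0. The 229 lower genes had a median of -0.28 at 12 h, with 54 above 0, and -0.01 at 24 h, with 108 above 0. These sets were chosen on the Pam3CSK4 array that the later differences also use, which pushes both medians toward the opposite sign. Against resting cells, 684 genes were at least 2-fold higher and 565 lower at 12 h, and 602 higher and 242 lower at 24 h.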

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

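Every test in this part was chosen after its result was seen, except the range of differences over the probe sets of a gene, which was fixed before its value was computed.

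TRPM1 differed from the Pam3CSK4 array in opposite directions at the 2 co-culture times, by -1.18 log2 at 12 h and 0.77 at 24 h. The difference between the times was not tested, with 1 array each. Its other probe set above the filter gave -0.62 and 0.24.

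Signal was also seen in data outside the comparisons, among the 4118 probe sets above the filter that the annotation table used here does not name. At 12 h 24 of them were at least 2-fold higher than with Pam3CSK4 and 8 lower. At 24 h 2 of them were higher, by 1.33 and 1.15 log2, and 0 lower.

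Gamma globin probe sets, and HBE1 at 24 h, stood far above both control arrays. The HBG1 and HBG2 difference was still at least 2.67 log2 after cyclic loess, which argues against a trend shared by genes of like level. As the deposited values already had a common distribution, loess had little left to remove. The largest HBB or HBD difference was 0.44 at 12 h and 0.0097 at 24 h. The smallest one of HBG1 and HBG2 exceeded it by 2.19 at 12 h and 3.37 at 24 h. That argues against cross-hybridisation shared with the HBB and HBD probe sets. HBE1, of the same family, was not part of this comparison. Binding of gamma globin transcripts to the HBE1 probe set stays open: its 12 h to 24 h difference exceeded the largest one of HBG1 and HBG2 by 0.24, short of the 0.5 set as decisive. RNA carried by the particles, whose source cells the labels do not name, may be the source. At 24 h 0 of 25 other members of the erythroid and megakaryocyte lists were at least 2-fold higher. At 12 h the megakaryocyte and platelet list stood above matched lists at 0.22, with 14 of 20 members above 0, but not with probe sets averaged. Neither result decides anything without a profile of the particles. Carried RNA and induction of globin genes in the THP-1 cells therefore cannot be told apart here.

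More genes differed from Pam3CSK4 at 12 h (102) than at 24 h (4). Compression of the 12 h array cannot be judged from cyclic loess, since the deposited values already had a common distribution. A level-dependent trend left in those values is argued against as the source of the count. After loess 104 genes were at least 2-fold different, among them 55 of the 55 higher and 36 of the 47 lower genes. Lower RNA quality at 12 h stays open, as the GAPDH control gap was 0.92 against 0.59 with Pam3CSK4. Of the 102 genes, 78.4% (80) lay further from resting than the Pam3CSK4 array. A gene that Pam3CSK4 barely moved lies further from resting after any such change, so this share decides nothing. Of the 555 genes higher with Pam3CSK4, 37 were at least 2-fold higher at 12 h and 8 lower. Of the 229 lower genes, 11 were lower at 12 h and 1 higher. A stronger Pam3CSK4-type response on the 12 h array stays a candidate explanation. The design does not separate particles, time since Pam3CSK4 and variation between single arrays, and none of them was tested.

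The genes higher with Pam3CSK4 came with an RNA quality difference, as the resting array had the widest gap between control probe sets. The list medians do not decide on it, since they are the pattern itself and random lists were matched on level and not on sensitivity to RNA integrity. For 429 higher genes outside the lists the question stays open: over the 195 with several probe sets, the median range was 0.78 log2, between the bounds of 0.5 and 1 set beforehand. For those genes the effect of the ligand and of RNA quality cannot be told apart.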

How the results depend on the processing

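The alternatives were fixed beforehand, except the smallest difference over a gene's probe sets, which was chosen after seeing the data. No paired analysis was possible because each group has 1 array. Leaving out a doubted array, such as the resting or the 12 h one, removes every comparison that uses it. The filter, the choice of probe set and the matching of random lists use all 4 arrays, so the other comparisons could change as well. No such run is given here. Counts follow as higher and lower. By construction, at 1.5-fold they were 1017 and 790 for Pam3CSK4 against resting, 255 and 383 at 12 h, 22 and 1 at 24 h, and 421 and 185 for 24 h against 12 h. At 3-fold they were 310 and 67, 12 and 6, 2 higher at 24 h, and 5 and 5. With probe sets averaged, 26 genes were lower at 12 h, 1 higher at 24 h and 21 higher at 24 h than at 12 h. The 75th percentile filter, at 8.01 log2, left 1 higher at 24 h, TDO2. HBE1, CALB1 and SOCS2 did not reach that level on any array. The smallest difference gave 29 lower at 12 h and 27 higher at 24 h than at 12 h. The other 43 counts stayed within 1.5 times. The correlation was 0.327 with the 75th percentile filter and 0.269 without _x_at and _s_at probe sets. The megakaryocyte and platelet median was 0.10 at 12 h when averaged, no longer apart, and 0.0775 at 24 h with no filter, then apart. The globin median was 0.16 at 12 h without _x_at and _s_at probe sets, where the HBG pair has no value. At 24 h it was -0.0097 with no filter, -0.0499 averaged and -0.0009 without those probe sets. Among other lists that stood apart, signs turned for monocyte genes at 12 h (0.0584), LXR and lipid genes at 24 h (0.0381) and unfolded-protein genes at 12 h (-0.0264), each without those probe sets, and for NRF2 and iron genes between the times when averaged (0.0298). Some lists inside the range turned sign as well, such as lysosomal genes at 12 h (0.1179 without those probe sets, against -0.0616). Beyond the cases noted, the cause was not tested. Of the named genes' values, 736 stayed at least 2-fold, 24 fell under it and none of those run changed sign. Under cyclic loess the counts were 581 and 206, 65 and 39, 4 and 0, and 35 and 35. Signal near background limits low genes: 164 of the 555 genes higher with Pam3CSK4 had a resting value under the filter level.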

Other observations

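The genes and the rule in this part were chosen after their values were seen. A few transcripts, globins among them, were at least 1.5-fold higher on both co-culture arrays than on both control arrays while the control arrays differed by less than 1.5-fold. These were CALB1, CCND2, CDKN2A, HBE1 and the HBG1 and HBG2 pair. CCND2, a G1 cyclin, was 0.91 log2 higher at 12 h and 0.87 at 24 h than with Pam3CSK4 on 1 of its 4 probe sets. That probe set passed the filter of 6.19 only in co-culture, at 6.35 and 6.31. It read 5.57 in resting cells and 5.44 with Pam3CSK4. The other 3, under the filter, gave 0.29 and 0.64, -0.04 and -0.05, and 0.21 and 0.22. CDKN2A, which encodes cell cycle inhibitors and is known to be deleted in THP-1 cells, was 0.80 higher at both times on 1 probe set of the _x_at kind. Its other probe sets, under the filter, gave 0.27 and 0.34, and -0.04 and -0.0075. CALB1 was also higher on its second probe set, under the filter, at 2.29 and 1.10.

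Of 12279 genes, 71 met the rule at 12 h and 8 at 24 h, and 5 met both. Both times share the 2 control arrays and the rule was set on genes already seen, so no test of chance is given, and the source of these transcripts was not tested. The CDKN2A probe set already read 6.50 log2 in resting cells. If the gene is deleted in these cells, which was not checked here, that signal was not specific to it or was background.

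COXFA4L3 and HMGN2P46, which went from 4.75 to 7.75 and from 6.58 to 9.02 log2 between the Pam3CSK4 and 12 h arrays, lie close together on chromosome 15 in the RefSeq table, with 7 entries between them. None of those 7 was measured above the filter. The 24 h array differed from the Pam3CSK4 array by 0.47 and 0.25 log2, and the Pam3CSK4 array from the resting one by 0.16 and 1.63.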
